A study of Rattus norvegicus with 11 samples.

How the data were processed

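Bulk RNA sequencing was analysed for 11 cultures of rat dorsal root ganglion (DRG) neurons, of which 3 were untreated, 4 received Schwann cell conditioned medium (SCCM) and 4 received prostaglandin E2 (PGE2) at 1 µM. Per the labels' protocols, ganglia came from Sprague-Dawley embryos at embryonic day 15, neurons were purified by immunopanning, treatment ran overnight from day 13 in vitro, and RNA was taken on day 14. Embryos of 1 pregnant rat (10 to 18 per experiment) made 1 biological replicate, per the series' design text, so p-values measure the spread between such cultures. RNA with an integrity number above 8 was used for poly-A enriched, stranded libraries, per the labels' protocols.

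The deposited values are FPKM (fragments scaled to transcript length and to mapped fragments), computed by the authors, with 1 column per library and 2 decimals. Rnor 6.0 is the genome build in the submitters' processing notes, and the aligner, the counting tool and the annotation are not given in the sources used here. The table held 22076 rows with values and 207489 lines without any, which were left out. Of the names, 18420 matched a symbol or synonym of the RefSeq gene table for the assembly GRCr8, used only for names because its build differs from that of the authors. Gene names from a spreadsheet had become dates in 2 rows. Of 926 genes in fixed lists, 894 had a row, and genes without one, such as Gapdh, Gfra1 and Col1a2, are not analysed here.

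Read totals are not given, so no counting interval could be set. FPKM of rarely seen genes fall on steps worth 1 fragment, and comparing those steps between libraries gave relative depth, with the deepest library 1.33-fold above the shallowest. All 990 checks of this ratio across sets of libraries closed within 0.1 on the log2 scale.

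Genes with a mean of at least 1 FPKM over the 11 libraries were tested (12107 genes). Values were transformed as log2(FPKM + 1), which understates the change of genes with low values, and log2 changes are on that scale. A single limma model with 3 groups (lmFit, contrasts.fit and eBayes with an intensity trend, limma 3.58.1, R 4.3.3) gave 3 comparisons, with two-sided moderated tests and Benjamini-Hochberg adjustment within each. A gene was called at an adjusted p under 0.05, and a second count also required a log2 change of at least 1. Because the values are FPKM, no count model was used.

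Gene lists, 28 in number, were fixed before the data were examined, as were the comparisons with their tests, the rule for naming genes and the alternatives other than the covariate named below. Tests of other cell types and of a wrong label were chosen after the results were seen. Of these, 26 had at least 3 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, then with the correlation estimated per list and with fry. Camera asks whether a list ranks above or below the other genes, whereas fry asks whether its members move on balance in 1 direction. P-values were adjusted over the 26 lists. Members were also adjusted over the list alone. The rule for naming genes took up to 8 called genes at each end per comparison, up to 4 called members per list or, with none called, up to 2 members with the largest absolute change, and always Ptger1 to Ptger4 and the 7 channel genes Scn1a, Scn2a, Scn3a, Scn8a, Scn9a, Scn10a and Scn11a. Genes named outside it are said to be chosen after their values were seen, apart from list members named because they passed the adjustment over the list alone.

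The tests were checked on simulated data with a set of changed genes, drawn from those with a mean log2(FPKM + 1) above 2. For SCCM against untreated, 35.8% of genes changed by a log2 value of 1 were recovered, 77.6% at 2 and 97.0% at 3. The same shares were 49.3%, 85.1% and 95.5% for PGE2 against untreated, and 56.7%, 94.0% and 97.0% for SCCM against PGE2. A list of 20 genes changed by 1 was called in 20 of 20 simulations, and 1 of 500 unchanged lists was called. Noise was drawn independently for each gene, so the simulations lack the correlation between genes, estimated at 0.654 for the proliferation list. They therefore do not give the rate of false list calls in these data. A split with both treatments on each side, untreated replicates 1 and 3 with SCCM replicates 1 and 4 against the rest, called 18 of 26 lists. That split was picked among those with many calls and does not give the rate either.

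Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, removal of the 13 mitochondrially encoded genes, fits of only the groups compared, eBayes without a trend or with robust settings, array weights, a replicate block, and leaving out each library in turn. A covariate for the hypoxia and glycolysis list was added after seeing the data. The mean of that list itself differed between groups (0.627 in untreated, −0.247 in SCCM and −0.223 in PGE2 libraries). The covariate can therefore also remove a treatment effect that moves with the list. Correlation between both responses was set against 100 simulations of unchanged groups with the same untreated libraries and 100 regroupings of the libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.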

Results

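The series asked how medium conditioned by Schwann cells, the glia that ensheathe peripheral axons, and PGE2, a lipid mediator that the series title describes as secreted by them, act on developing sensory neurons. Transcript levels were measured in immunopanned rat DRG neurons left untreated (n = 3) or treated overnight with SCCM (n = 4) or 1 µM PGE2 (n = 4). Between 15664 and 17137 genes had FPKM above 0 in a library, and between 11312 and 12327 reached 1 FPKM. Sequencing depth differed by at most 1.33-fold, as judged from the steps in the values of rarely seen genes.

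Tubb3, which encodes a neuronal tubulin, lay between 828 and 1659 FPKM in every library. Of the markers of Schwann cells and satellite glia with a row, 15 of 26 stayed under 1 FPKM in every library, as did 16 of 21 fibroblast and meningeal markers, 15 of 19 endothelial and mural markers and 18 of 20 macrophage and immune markers. The other 11 glial markers reached 1 FPKM in some library, and the most abundant, chosen after their values were seen, were Ngfr (29.1 to 260.02 FPKM), Pmp22 (21.6 to 84.95 FPKM) and Scn7a (13.9 to 80.05 FPKM).

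Libraries of the same treatment differed widely. The first principal component held 56.0% of the variance, and scores ran from −60.8 to −7.68 in untreated, from −27.9 to 45.5 in SCCM and from −37.6 to 55.8 in PGE2 libraries. Among the genes that weighed most on it, chosen after their values were seen, Nefh, a heavy neurofilament subunit, lay between 7.81 and 145 FPKM and the itch-receptor family gene Mrgprx4 between 0.58 and 107 FPKM, with high values at the positive end. At the negative end, Adm, which encodes the peptide adrenomedullin, lay between 0.15 and 56.5 FPKM and Cd68, a lysosomal gene on the macrophage list, between 0.04 and 45.1 FPKM. SCCM replicates 2 and 3 lay with PGE2 replicates 3 and 4, whereas SCCM replicate 1 and PGE2 replicates 1 and 2 lay among the untreated libraries. Among the gene lists, median loadings on this component stood at percentile 96.1 of all genes for voltage-gated calcium channels, 95.9 for sodium channels 91.2 for voltage-gated potassium channels and 87.4 for Schwann and satellite glia markers, and at 4.39 for hypoxia and glycolysis genes, 11.9 for genes induced by cAMP and activity and 14.1 for proliferation genes. Mitochondrially encoded genes made up 8.06, 7.86 and 8.14% of FPKM in SCCM replicate 2 and PGE2 replicates 3 and 4 and 3.71% in SCCM replicate 3, against 3.20 to 5.54% in the libraries with negative scores. The 10 most abundant genes took 9.26 to 11.2% in those 4 libraries against 6.70 to 7.70%, and 15664 to 15946 genes were above 0 FPKM against 15954 to 17137. SCCM replicate 4, at a score of 7.62, had 10.9% mitochondrial FPKM and 11.97% in its 10 most abundant genes. Rank correlations across genes between libraries of 1 group (0.945 to 0.976) covered much the same range as those between groups (0.931 to 0.982). The highest, for untreated replicate 2 with PGE2 replicate 2, and the lowest, for untreated replicate 3 with PGE2 replicate 4, were both between groups.

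**Figure D1:**
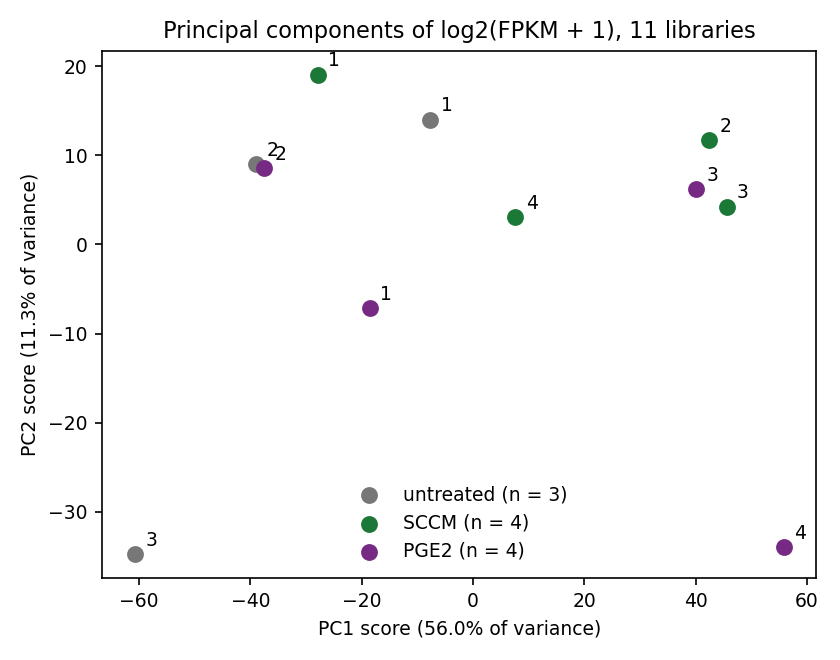
Principal component scores of log2(FPKM + 1), with PC1 (56.0% of variance) on the horizontal and PC2 (11.3%) on the vertical axis; each point is a library, colored by group and labelled by replicate number. SCCM libraries reach from −27.9 to 45.5 and PGE2 libraries from −37.6 to 55.8 on PC1.

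SCCM was first compared with no treatment. Voltage-gated sodium channel transcripts were higher on average: Scn10a, a channel of nociceptors, measured 67.3 ± 28.2 FPKM in SCCM (SD, n = 4) against 20.003 ± 10.4 FPKM untreated (SD, n = 3), a log2 change of 1.71 (SE 0.56). Scn9a differed by 1.30 (SE 0.56) and Scn11a by 1.17 (SE 0.43). Of the 11 tested sodium channel genes, 11 had higher means under the deposited scale and under each of 3 other scalings, with a median log2 change of 0.67 against −0.13 over all tested genes. Limma's camera called the list as higher (adjusted p = 2.0e-05, but adjusted p = 0.386 with an estimated correlation). None of the 11 passed limma alone. Scn1a, Scn2a, Scn3a and Scn8a differed by 0.67, 0.26, 0.66 and 0.92. With the hypoxia and glycolysis list as a covariate, chosen after seeing the data, Scn1a, Scn2a and Scn8a differed by −0.059, −0.022 and −0.011. That list was itself lower in SCCM, so the covariate can also remove a treatment effect that moves with it. Over all alternatives Scn9a ranged from 0.37 to 1.67, Scn10a from 0.94 to 2.08 and Scn11a from 0.53 to 1.82, each lowest with that covariate. The sodium channel transcripts moved with the first principal component, on which SCCM libraries averaged 16.9 and untreated libraries −35.8.

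Other groups of neuronal genes were called by camera in the same direction. Members with higher means numbered 28 of 33 for voltage-gated potassium channels (median 0.35, adjusted p = 2.0e-05), 16 of 17 for voltage-gated calcium channels (0.52, 9.4e-06) and 31 of 40 for synaptic vesicle and release genes (0.32, 2.0e-05). With an estimated correlation the adjusted p was 0.386 for each of these lists. Examples were Kcnmb4 (log2 change 0.94), Kcnc4 (0.90), Cacng8 (1.27), Cacna2d1 (0.93), Cadps (1.22) and Syt2 (0.96). Neurotransmitter receptors (28 of 42 members higher, adjusted p = 0.0016), cAMP and PKA signalling (21 of 36, 0.0094) and sensory transduction channels (12 of 20, 0.028) were also called, each with adjusted p = 0.386 with an estimated correlation. Their examples were Htr1b at 1.72 and Chrm4 at −1.61, Rapgef4 at 1.26 and Prkar2b at 1.21, and Piezo2, a mechanosensitive channel, at 1.36 and Trpm3 at 1.35. Pan-neuronal genes (18 of 28 higher, adjusted p = 0.0029, or adjusted p = 0.472 with an estimated correlation) included Nefh at 1.80 (0.64 with the covariate) and Nefl at 0.90. Axon guidance and adhesion genes (28 of 44 higher, adjusted p = 0.013, or adjusted p = 0.457 with an estimated correlation) included Chl1 at 1.56 and Efnb1 at −2.00. With median-ratio scaling, which put the median of all genes at −0.0014, members with higher means numbered 24 of 28 for pan-neuronal genes (median 0.39), 36 of 40 for synaptic genes, 30 of 33 for potassium channels, 32 of 42 for receptors, 25 of 36 for cAMP and PKA signalling, 13 of 20 for sensory transduction channels and 29 of 44 for axon guidance genes.

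Hypoxia and glycolysis genes had lower means for 28 of 31 members (median −0.77), with Adm at −2.998 (SE 1.35) and Ankrd37, a hypoxia-induced gene, at −2.52 (SE 1.09). Integrated stress and unfolded protein response genes were lower for 29 of 32 members (median −0.56), among them Fgf21, a secreted hormone induced by stress, which measured 119 ± 153 FPKM in SCCM (SD, n = 4) and 519 ± 46.6 FPKM untreated (SD, n = 3), and Gdf15 at −2.27. Proliferation genes were lower for 15 of 16 members (median −0.56), with Mcm6 at −1.44 and Ube2c at −1.15. Camera called the lists as lower with adjusted p of 0.0035, 0.0053 and 0.019. With an estimated correlation the adjusted p was 0.683, 0.639 and 0.683.

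Cytokine and JAK-STAT response genes were called as higher (12 of 20 members, median 0.17, or 0.28 with median-ratio scaling, adjusted p = 0.040, or adjusted p = 0.386 with an estimated correlation). Ccl2, a monocyte chemoattractant, measured 44.4 ± 26.8 FPKM in SCCM (SD, n = 4) and 4.58 ± 5.02 FPKM untreated (SD, n = 3), a log2 change of 3.33 (SE 0.80). Ccl2, Stat3 (0.82) and Nfkb2 (−1.36) passed when adjusted over the list alone, 3 of 20 members, against 0 over all genes. In the TGF-beta and BMP list, whose camera test was not passed (adjusted p = 0.815), Id1, a BMP-induced regulator, at −2.30, Tgfbi at 1.76 and Pmepa1, a feedback inhibitor of TGF-beta signalling, at 1.53 passed when adjusted over the list alone. In the interferon list (adjusted p = 0.455) B2m at −0.79 did so. Among the genes with the lowest p, chosen after their values were seen, Sbno2, a transcriptional co-regulator, differed by 1.83 (SE 0.30) and Tmem60 by −0.81 (SE 0.15). Reg3b, a secreted lectin, was listed at 0 in all untreated libraries and at 1.33, 5.01, 17.2 and 26.5 FPKM in the SCCM libraries.

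Limma called 0 of 12107 genes for SCCM against untreated (lowest adjusted p = 0.357). There were 1648 at an unadjusted p under 0.05 (587 higher, 1061 lower), where 605 are expected by chance. As many were reached by 4 of 35 splits of these libraries, a count that, as in the later comparisons, includes the split of the labels. The 1648 became 401 without untreated replicate 3, 631 without SCCM replicate 3, 699 without SCCM replicate 2 and 956 without untreated replicate 2. They became 2662 without untreated replicate 1 and 3060 without SCCM replicate 1, and 772 with a replicate block and 547 with the hypoxia and glycolysis covariate. Values of all 3 untreated and all 4 SCCM libraries did not overlap for 1282 genes (10.6%, chance 5.71%). Array weights called 7314 genes (1962 higher, 5352 lower), with a weight of 41.1 on untreated replicate 2 and at most 1.89 on any other library, and leaving out SCCM replicate 1 called 1 gene, Reg3b (adjusted p = 0.048). Without untreated replicate 3, camera no longer called sensory transduction channels (adjusted p = 0.117), cAMP and PKA signalling (0.117), pan-neuronal (0.144), proliferation (0.177), cytokine (0.122), stress response (0.054), axon guidance (0.364) or receptor genes (0.117), sensory transduction channels were also lost without SCCM replicate 3 (0.064), and cytokine genes without SCCM replicate 1 (0.064) or PGE2 replicate 3 (0.050).

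**Figure D2:**
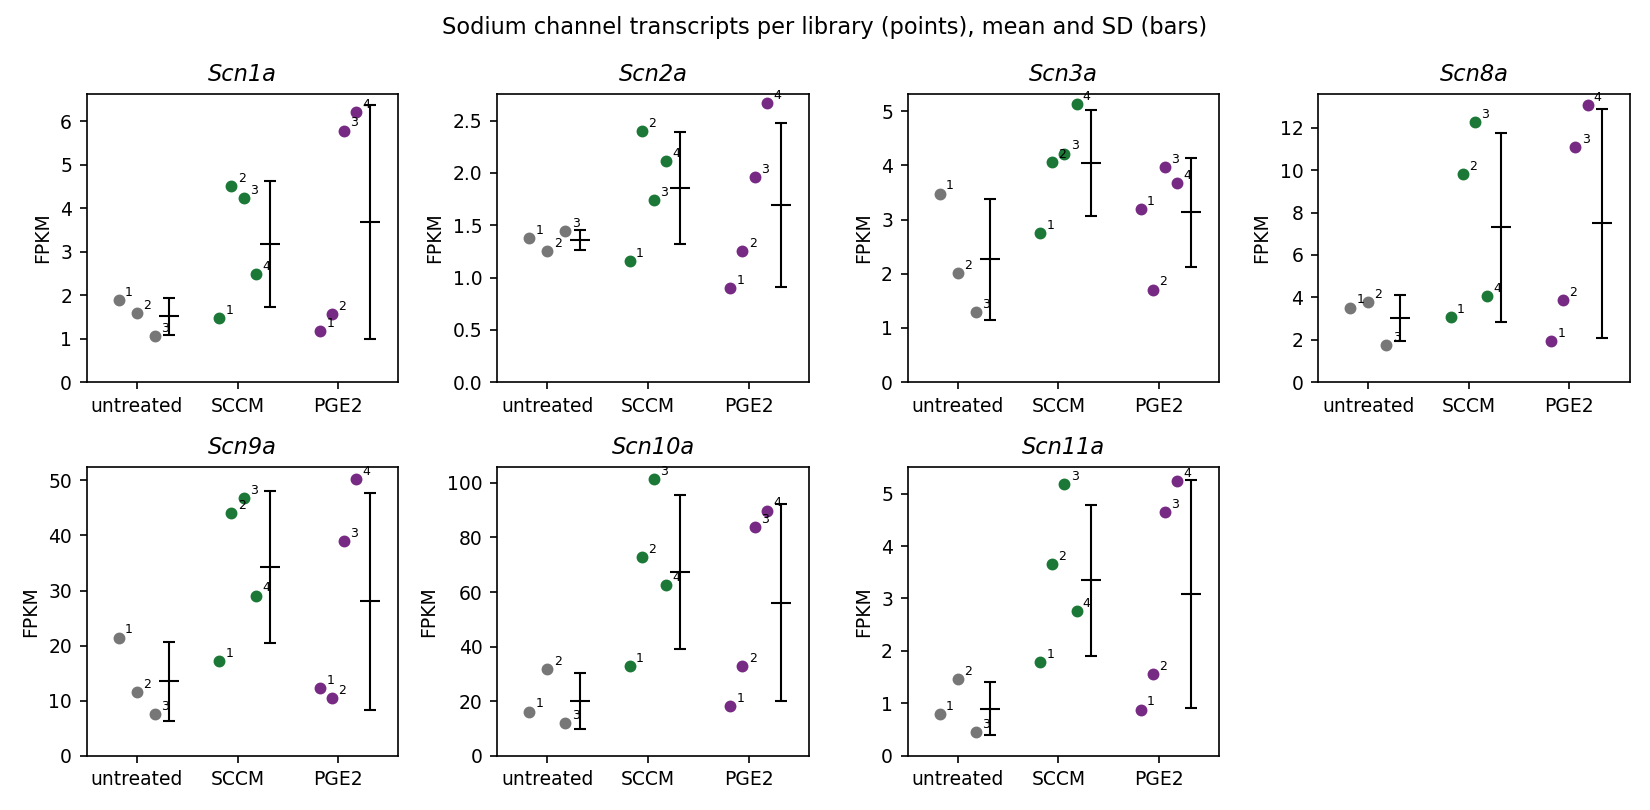
FPKM (vertical axis) of 7 sodium channel genes by group, with each point a library labelled by replicate number and bars the mean and SD (n = 3 untreated, 4 SCCM, 4 PGE2). Scn10a spans 12.1 to 31.8 FPKM in untreated, 32.9 to 101 in SCCM and 18.1 to 89.8 in PGE2 libraries.

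PGE2 was compared with no treatment in the same fit. Sodium channel transcripts again had higher means for 11 of 11 members under all 4 scalings (median log2 change 0.71 against −0.16 over all tested genes). Scn10a measured 56.1 ± 36.0 FPKM (SD, n = 4) and differed by 1.28 (SE 0.56), Scn11a by 0.96 (SE 0.43), Scn8a by 0.85 (SE 0.57) and Scn9a by 0.82 (SE 0.56), while Scn1a, Scn2a and Scn3a differed by 0.71, 0.15 and 0.36. Without PGE2 replicate 4 Scn2a differed by −0.015. With the hypoxia and glycolysis covariate, Scn1a, Scn2a, Scn8a and Scn9a differed by −0.0064, −0.12, −0.055 and −0.084. Over all alternatives Scn10a ranged from 0.23 to 1.72 and Scn11a from 0.32 to 1.47, each lowest with array weights. Camera called the list (adjusted p = 1.0e-05, or adjusted p = 0.308 with an estimated correlation). PGE2 replicates 1 and 2, at 18.1 and 32.9 FPKM of Scn10a, lay near the untreated range of 12.1 to 31.8, and PGE2 replicates 3 and 4 at 83.7 and 89.8.

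Synaptic vesicle and release genes had the lowest p of any list (32 of 40 members higher, median 0.33, adjusted p = 2.9e-10, or adjusted p = 0.308 with an estimated correlation), with Cadps, a factor for dense-core vesicle release, at 1.22 (SE 0.42) and Pclo at 1.13. Voltage-gated potassium channels (28 of 33 higher, adjusted p = 5.6e-08, or adjusted p = 0.308 with an estimated correlation) included Kcnab2 at 1.02 and Kcnip3 at 0.97. Pan-neuronal genes (21 of 28 higher, adjusted p = 3.6e-06, or adjusted p = 0.308 with an estimated correlation) included Nefh at 1.27 (0.14 with the covariate) and, against the list's direction, the transcription factor Isl1 at −1.06 (SE 0.33). Sensory transduction and pacemaker channels (11 of 20, 0.0063) included Piezo2 at 1.14, and cAMP and PKA signalling genes (21 of 36, 0.0033) included Adcy1 at 1.06 and Rapgef4 at 0.96. Both of these lists had adjusted p = 0.308 with an estimated correlation. Calcium channels (14 of 17 higher, 1.2e-05, or adjusted p = 0.356 with an estimated correlation) included Cacng2 at 0.92 and Cacna2d3 at 0.87. Receptor genes (27 of 42 higher, 5.9e-04, or adjusted p = 0.367 with an estimated correlation) included Chrna3 at 1.56 and Chrm4 at −1.19. With median-ratio scaling, which put the median of all genes at −0.0033, members with higher means numbered 15 of 20 for sensory transduction channels, 27 of 36 for cAMP and PKA signalling, 37 of 40 for synaptic genes, 31 of 33 for potassium channels, 24 of 28 for pan-neuronal genes, 15 of 17 for calcium channels and 30 of 42 for receptors.

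Lower means were found for 28 of 31 hypoxia and glycolysis genes (median −0.85, adjusted p = 0.0021, or adjusted p = 0.657 with an estimated correlation), with Adm at −2.50 and Ankrd37 at −2.33. Proliferation genes were lower for 15 of 16 members (median −0.47, adjusted p = 0.0498, or adjusted p = 0.662 with an estimated correlation), with Mcm6 at −1.22 and Ube2c at −0.98. Genes induced by cAMP, a second messenger of some PGE2 receptors, and by neuronal activity were not called (26 of 33 lower, adjusted p = 0.231), with Junb at −1.53, or 0.090 with the hypoxia and glycolysis covariate, and Dusp4 at −1.50. In the TGF-beta and BMP list, also not called (adjusted p = 0.059, or 0.013 with a replicate block), Id1 differed by −2.20 (SE 0.63). Of genes with the lowest p, chosen after their values were seen, Styx differed by −0.72 (SE 0.18) and Erf, a repressor of the ETS family, by −1.04 (SE 0.27).

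Limma called 0 of 12107 genes for PGE2 against untreated (lowest adjusted p = 0.538), with 692 at an unadjusted p under 0.05 (203 higher, 489 lower) where 605 are expected, a number that 11 of 35 splits of these libraries reached, and 2 genes with array weights. The 692 became 185 without untreated replicate 3, 251 without PGE2 replicate 4, 255 without PGE2 replicate 3 and 347 without untreated replicate 2. They became 1791 without untreated replicate 1 and 2301 without PGE2 replicate 2. With a replicate block there were 229, with the hypoxia and glycolysis covariate 152 and with array weights 3730. No overlap between the groups was seen for 645 genes (5.33%, chance 5.71%), and no list member passed when adjusted over the list alone. Without untreated replicate 3, camera no longer called cAMP and PKA signalling (adjusted p = 0.111), receptor genes (0.196) or proliferation genes (0.493), and the last were also lost without SCCM replicate 1 (0.050), PGE2 replicate 1 (0.053), PGE2 replicate 3 (0.132) or PGE2 replicate 4 (0.099), or with a replicate block (0.083).

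**Figure D3:**
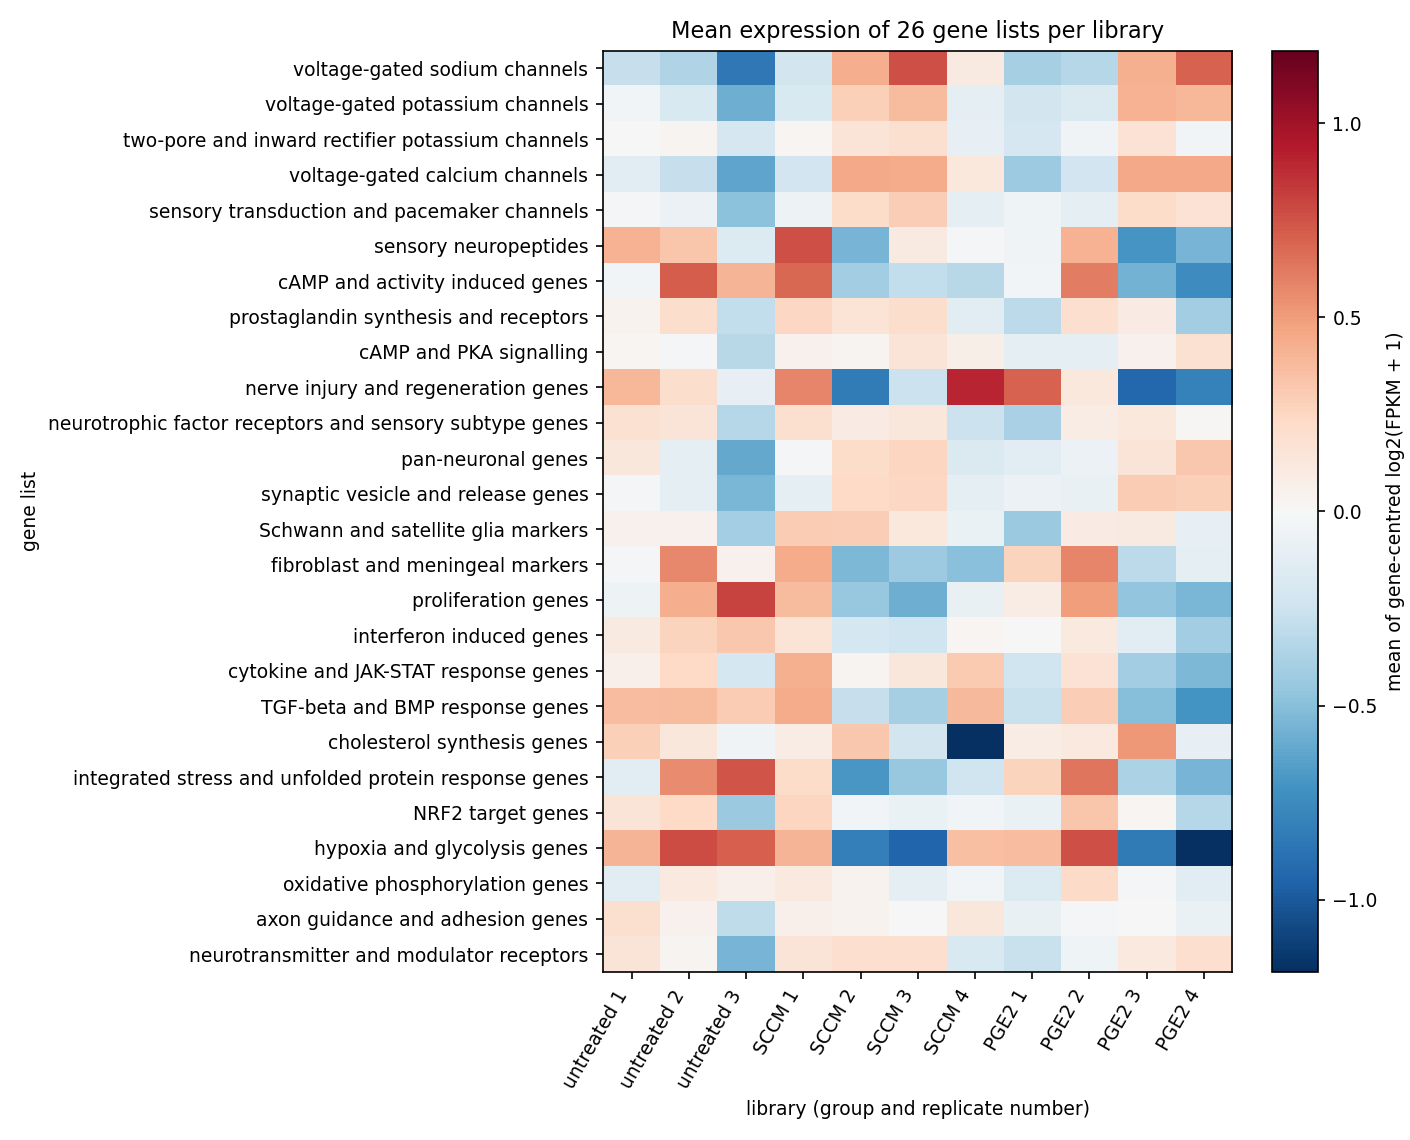
Mean of gene-centred log2(FPKM + 1) for 26 gene lists (vertical axis) in each of 11 libraries (horizontal axis, group and replicate number), from blue (low) to red (high). Hypoxia and glycolysis genes range from −1.18 in PGE2 replicate 4 to 0.77 in untreated replicate 2, and cholesterol synthesis genes reach −1.19 in SCCM replicate 4.

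The direct comparison of SCCM with PGE2 asks where the conditioned medium differs from PGE2 alone. Sbno2 was higher in SCCM, at 12.9 ± 3.55 FPKM (SD, n = 4) against 1.68 ± 0.719 FPKM in PGE2 (SD, n = 4) and 3.00 ± 1.30 FPKM untreated (SD, n = 3). The log2 change was 2.38 (SE 0.27, 95% interval 1.78 to 2.98, limma adjusted p = 0.028), and all 4 SCCM libraries (9.62 to 17.9 FPKM) lay above all 4 PGE2 libraries (0.99 to 2.69 FPKM). Against untreated libraries, Sbno2 differed by −0.56 in PGE2 (limma adjusted p = 0.538). Limma called no other gene, with 397 at an unadjusted p under 0.05 (304 higher, 93 lower) where 605 are expected and 15 of 35 splits reached as many, and 267 genes did not overlap (2.21%, chance 2.86%). The 397 became 248 without SCCM replicate 4, 254 without PGE2 replicate 1, 619 without PGE2 replicate 3 and 621 without SCCM replicate 1. They became 806 with the hypoxia and glycolysis covariate and 1342 with array weights. Over 23 alternatives the log2 change of Sbno2 lay between 2.22 and 2.92 and the adjusted p between 0.010 and 0.606, under 0.05 in 12, and the call ended with a pseudocount of 0.1 (0.057), without a filter (0.140) and with a replicate block (0.606). It also ended without untreated replicate 2 (0.073), SCCM replicate 1 (0.061, where Reg3b was called instead), SCCM replicate 2 (0.067), SCCM replicate 3 (0.168), SCCM replicate 4 (0.141), PGE2 replicate 1 (0.172), PGE2 replicate 3 (0.168) or PGE2 replicate 4 (0.142).

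Cytokine and JAK-STAT response genes were called as higher in SCCM (14 of 20 members, median 0.39, adjusted p = 0.0010, or adjusted p = 0.317 with an estimated correlation). Ccl2 (log2 change 2.66), Socs3, a feedback inhibitor of JAK-STAT signalling (1.75), Timp1 (1.45) and Stat3 (0.76) passed when adjusted over the list alone, 4 of 20 members, against 0 over all genes. The TGF-beta and BMP list was called as higher (adjusted p = 0.014, or adjusted p = 0.685 with an estimated correlation), although its median was −0.01 and its mean 0.34, with 6 of 13 members higher. Tgfbi (1.76), Pmepa1 (1.58), Fst (0.91), Skil (0.85) and Ski (0.57) passed when adjusted over the list alone. Nptx2, an activity-induced pentraxin, at 1.54 and Irf9, a subunit of the interferon-stimulated transcription factor, at 1.16 did so in their lists, which camera did not call (adjusted p = 0.886 and 0.971). Of genes with the lowest p, chosen after their values were seen, Ier5l differed by 1.77 (SE 0.34) and Erf by 1.20 (SE 0.25), and Reg3b was listed at 0 in 3 PGE2 libraries and at 0.09 FPKM in PGE2 replicate 1.

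**Figure D4:**
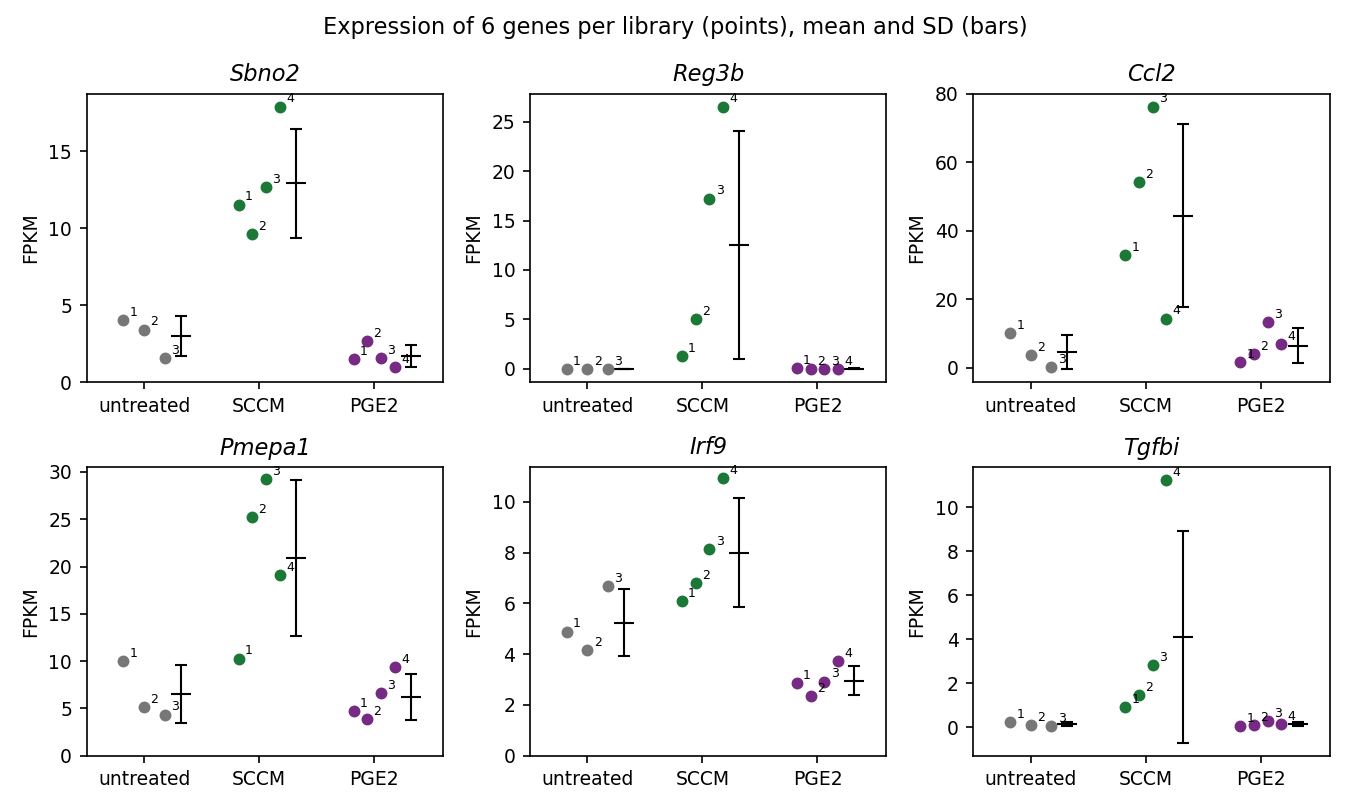
FPKM (vertical axis) of 6 genes by group, with each point a library labelled by replicate number and bars the mean and SD (n = 3 untreated, 4 SCCM, 4 PGE2). Sbno2 spans 9.62 to 17.9 FPKM in SCCM and 0.99 to 2.69 FPKM in PGE2 libraries; only Sbno2, in SCCM against PGE2, was called.

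Cholesterol synthesis genes were lower in SCCM than in PGE2 for 24 of 24 members under all 4 scalings (median −0.42, camera adjusted p = 8.2e-08, or adjusted p = 0.685 with an estimated correlation), with the enzyme Mvd at −0.74 and the sterol sensor partner Insig1 at −0.70. SCCM replicate 4 carried much of this, with a list mean of −1.19 where the other SCCM libraries lay between −0.22 and 0.32, and without it the adjusted p was 0.116. Integrated stress genes were lower for 27 of 32 members (median −0.21, adjusted p = 0.0010, or adjusted p = 0.958 with an estimated correlation), with Ddit3 at −1.18 and Fgf21 at −1.15. Without PGE2 replicate 2 the adjusted p of that list was 0.103, and the TGF-beta list was lost without SCCM replicate 1 (0.061) or PGE2 replicate 3 (0.144).

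Sodium channels did not separate SCCM from PGE2. Scn9a differed by 0.48 (95% interval −0.66 to 1.61), Scn10a by 0.43 (−0.71 to 1.56) and Scn11a by 0.21 (−0.66 to 1.08), and Scn1a, Scn2a, Scn3a and Scn8a by −0.03, 0.11, 0.30 and 0.07. Camera did not call the list (adjusted p = 0.369, with 9 of 11 members higher), and limma called none of these genes (adjusted p = 1.00), which at this spread does not show that levels were alike. Without PGE2 replicate 1 the differences were −0.0096 for Scn10a, −0.11 for Scn11a, −0.35 for Scn8a and −0.045 for Scn2a, and Scn8a also turned without SCCM replicate 2 (−0.11), SCCM replicate 3 (−0.21) or PGE2 replicate 2 (−0.11). Scn1a turned without SCCM replicate 1 (0.19), SCCM replicate 4 (0.031), PGE2 replicate 3 (0.21) or PGE2 replicate 4 (0.24). Tac1, the substance P precursor, differed by 1.19 (SE 0.49) and Chl1 by 1.08 (SE 0.39), and neither was called.

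The PGE2 receptor genes were not called in any comparison. Ptger1, Ptger2, Ptger3 and Ptger4 measured 2.82, 5.16, 0.983 and 1.03 FPKM in untreated libraries, 4.37, 3.48, 1.90 and 1.71 FPKM in SCCM and 2.96, 4.87, 1.51 and 0.583 FPKM in PGE2. Log2 changes were 0.66, −0.20, 0.45 and 0.35 for SCCM against untreated and 0.17, 0.12, 0.33 and −0.37 for PGE2 against untreated. For SCCM against PGE2 they were 0.49, −0.32, 0.12 and 0.72, with 95% intervals of −0.24 to 1.21, −1.71 to 1.07, −0.49 to 0.74 and 0.07 to 1.37. Directions turned with single libraries: without untreated replicate 2, Ptger2 differed by 0.44 for SCCM against untreated, and without SCCM replicate 4 by 0.12. For PGE2 against untreated, Ptger1 and Ptger2 differed by −0.26 and −0.66 without untreated replicate 3 and by −0.026 and −0.17 without PGE2 replicate 3, and Ptger2 by −0.11 without PGE2 replicate 2. For SCCM against PGE2, Ptger2 differed by 0.00021 without SCCM replicate 4 and Ptger3 by −0.14 without SCCM replicate 3. The list of prostaglandin synthesis and receptor genes was not called (adjusted p = 0.157, 0.625 and 0.270).

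Log2 changes of the treatments against untreated correlated across the 12107 genes (Pearson r = 0.826, genes not being independent replicates), with the same sign for 83.03%. Unchanged groups set against the same untreated libraries gave r = 0.571 in simulation. The covariance was 0.178 against 0.0734 in simulation, a difference of 0.105. The simulation drew genes independently of one another, so it does not give the spread of these values. Regrouping the 11 libraries at random gave r between −0.17 and 0.91 (median 0.66), and 17 of 100 regroupings reached the observed value. For the covariance, regrouping gave −0.025 to 0.298 (median 0.071), and 18 of 100 regroupings reached the observed value. No gene was called in either comparison, so no overlap of calls could be set against chance. The 3 untreated libraries cannot be split into parts of at least 2 libraries each, and part of the correlation and of the same-sign share can come from sharing them.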

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

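The tests of other cell types and of a wrong label were chosen only after the results were seen, and those of scaling and depth were planned. Of 82 groups of 4 libraries tested for a library far from the others, 4 held one, and chance gives about 4.1. In SCCM replicate 1, the list mean of genes induced by cAMP and activity was 0.68, against −0.41 to −0.29 in the other SCCM libraries. In the same library, the fibroblast and meningeal list mean was 0.44, against −0.53 to −0.43. Its NRF2 target mean was 0.25, against −0.08 to −0.03. In SCCM replicate 4, the neurotransmitter and modulator receptor mean was −0.18, against 0.15 to 0.20.

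Libraries of the same treatment lay at both ends of the first principal component, from −27.9 to 45.5 in SCCM and from −37.6 to 55.8 in PGE2. Carry-over of fibroblasts, endothelial cells and macrophages is argued against by Col1a1, Col3a1, Fn1, Cdh5, C1qb and Csf1r, picked after the results were seen. They reached at most 0.26 FPKM in any library. On the same lists, however, Col6a2 reached 13.3 FPKM in untreated, 10.5 in SCCM and 10.3 in PGE2 libraries, and Cd68 reached 45.1 FPKM. Schwann and satellite glia were not covered by this test, and their list stood at percentile 87.4 on this component. Their carry-over stays open. A few abundant genes setting the scale are also argued against, since the component held 53.8% of variance without mitochondrial genes after median-ratio scaling, and so is depth acting through sparsely sampled genes, since it held 57.6% among 1552 genes of at least 50 FPKM. Relative depth was nonetheless 0.914 to 0.986 of that of the deepest library in SCCM replicates 2 and 3 and PGE2 replicates 3 and 4, against 0.763 to 1.00 in the libraries with negative scores, so an association of depth with the component by another route stays open. A difference between cultures in oxygen supply, stress or maturation may underlie it and stays open, since the labels give no such group and no biological explanation was tested.

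SCCM replicate 1 lay at −27.9 on that component, within the untreated range. Of 39 genes chosen as higher in the other 3 SCCM libraries, it exceeded every untreated and PGE2 library for 12 (30.8%). Untreated libraries held out in the same way gave 30.9%, 2.38% and 9.09% and PGE2 libraries 2.70%, 2.56%, 82.5% and 53.4%, so a wrong label was not excluded, and the shares of PGE2 replicates 3 and 4 show that a high share does not mark an SCCM library. Some single genes go against a wrong label. Reg3b, called when SCCM replicate 1 was left out, was at least 1.33 FPKM in every SCCM library and 0 in all untreated libraries. Sbno2 was at least 9.62 FPKM in every SCCM library, against at most 4.04 untreated and 2.69 in PGE2. Tgfbi was at least 0.94 FPKM against at most 0.25 and 0.28. Sbno2 and Tgfbi were picked with that library in the fit, and the 39 genes as a set do not decide. Neither a wrong label nor a weaker response of that culture was excluded.

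The call of Sbno2 in SCCM against PGE2 is not separated from chance by the splits of the libraries, of which 3 of 35, that of the labels included, called at least 1 gene.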

How the results depend on the processing

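The hypoxia and glycolysis covariate was chosen after seeing the data; the cause was not tested for any change given here unless stated. Of 2553 values of 113 named gene results under alternatives, 2461 kept direction and side of the threshold, 47 passed it (45 with array weights), 11 no longer did and 34 reversed. Only 1 of these results, Sbno2 in SCCM against PGE2, was called in the main fit, so for the others keeping the side meant staying uncalled. The 11 were all of Sbno2, which was called in 12 of 23 alternatives. Counts of called genes were 7314 and 2 with array weights against untreated (SCCM and PGE2), where a weight of 41.1 fell on untreated replicate 2. For SCCM against PGE2 they were 0 with a pseudocount of 0.1, 0 without a filter (more genes tested), 0 with a replicate block and 2 (Mt1 and Sbno2) with the covariate. The values showed no clear pairing of libraries by replicate number. Of 10 same-number pairs, 3 had a correlation of deviations over 0.1 (range −0.506 to 0.493), and 2 of 11 libraries correlated best with their own number. The highest correlations joined unlike numbers across treatments. They were 0.723 for SCCM replicate 1 with PGE2 replicate 2, 0.696 for SCCM replicate 2 with PGE2 replicate 3 and 0.591 for SCCM replicate 3 with PGE2 replicate 4. The replicate block does not model such pairs. With 56.0% of variance on 1 component, this check cannot exclude litters or culture days shared under 1 number or across numbers. The block called 13, 13 and 4 lists. For PGE2 against untreated it lost proliferation genes (camera adjusted p = 0.083). It gained TGF-beta (0.013), cholesterol (8.2e-05), NRF2 (0.022) and oxidative phosphorylation genes (0.020), with no other list call changed. Leaving out each library gave 0 to 1 genes for SCCM against untreated, 0 for PGE2 against untreated and 0 to 1 for SCCM against PGE2. Called lists numbered 0, 0 and 0 with correlation estimated per list and 0, 0 and 0 with fry, and without 1 library 6 to 16, 9 to 14 and 3 to 8. The correlation of both responses lay between 0.727 and 0.893 without 1 library. With the covariate, log2 changes were −0.059 for Scn1a, −0.022 for Scn2a and −0.011 for Scn8a (SCCM against untreated), and −0.0064 for Scn1a, −0.12 for Scn2a, −0.055 for Scn8a, −0.084 for Scn9a and 0.090 for Junb (PGE2 against untreated). With the replicate block Ptger2 differed by 0.017 (SCCM against untreated). With array weights Ptger4 differed by −0.086 (SCCM against untreated), Ptger2 by −1.27 (PGE2 against untreated) and Scn1a by 0.47 (SCCM against PGE2), and with a pseudocount of 0.1 Scn1a by 0.013 (SCCM against PGE2). Without 1 library, Ptger2 ranged from −0.98 to 0.44 for SCCM against untreated. For PGE2 against untreated, Scn2a ranged from −0.015 to 0.30, Ptger1 from −0.26 to 0.61 and Ptger2 from −0.66 to 0.76. For SCCM against PGE2, Scn1a ranged from −0.33 to 0.24, Scn2a from −0.045 to 0.27, Scn8a from −0.35 to 0.40, Scn10a from −0.0096 to 0.74, Scn11a from −0.11 to 0.47, Ptger2 from −0.72 to 0.00021 and Ptger3 from −0.14 to 0.34. Read totals are unknown, so what depth limits was not analysed here.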

Other observations

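The list tests and the counts of called genes and called lists over splits were planned. Split counts of genes at an unadjusted p under 0.05 were not in that plan. Sensory neuropeptide genes were not called by limma's camera in any comparison (adjusted p = 0.878, 0.885 and 0.886 for SCCM against untreated, PGE2 against untreated and SCCM against PGE2), and for SCCM against untreated their median was −0.32 although the test ranked them upward. Tac1, the substance P precursor, measured 39.5 ± 25.7 FPKM in SCCM (SD, n = 4) and 7.71 ± 3.08 FPKM untreated (SD, n = 3), a log2 change of 2.03 (SE 0.53), and Ucn differed by −1.55. Genes induced by cAMP and activity were not called for SCCM against untreated (adjusted p = 0.430, median −0.50), with Fosb at −1.58 and Egr4 at −1.47. Nerve injury and regeneration genes were not called (adjusted p = 0.130, 0.780 and 0.135); their median for SCCM against untreated was −0.09, upward by the test and 0.09 with quantile normalization. Neurotrophic factor receptors and sensory subtype genes (0.358, 0.297 and 0.971) and two-pore and inward rectifier potassium channels (0.226, 0.235 and 0.917) were not called either.

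Schwann and satellite glia markers had 9 tested members and were not called (adjusted p = 0.083, 0.297 and 0.270), with medians of 0.38, 0.15 and 0.23. Fibroblast and meningeal markers had 3 (0.851, 0.318 and 0.232), with a median of 0.03 and a mean of −0.46 for SCCM against untreated and of 0.22 and −0.10 for PGE2 against untreated. Endothelial and macrophage lists had 1 tested member each and were not tested. Oxidative phosphorylation genes (0.146, 0.064 and 0.971) had medians of −0.02 and −0.03 against untreated, which became 0.13 and 0.15 with median-ratio scaling, and with a replicate block the list was called for PGE2 against untreated (adjusted p = 0.020). NRF2 targets (0.130, 0.068 and 0.971) were not called, but were for PGE2 against untreated with a replicate block (adjusted p = 0.022). Cholesterol synthesis genes were not called against untreated (0.079 for SCCM, lower for 19 of 24 members, and 0.078 for PGE2, or 8.2e-05 for PGE2 with a replicate block). Interferon-induced genes (0.235), integrated stress genes (0.387), cytokine genes (0.795) and axon guidance genes (0.064, median −0.01, or 0.12 with median-ratio scaling) were not called for PGE2 against untreated. For SCCM against PGE2, axon guidance genes (0.270), calcium channels (0.270), synaptic genes (0.270), pan-neuronal genes (0.369), proliferation genes (0.490), potassium channels (0.850), hypoxia genes (0.850), receptors (0.850), cAMP and PKA signalling (0.886) and sensory transduction channels (0.971) were not called.

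Splits of the libraries into groups of the same sizes, 35 per comparison with that of the labels included, did not exclude chance for the counts above 0. Limma called 0 genes for SCCM against untreated and 0 for PGE2 against untreated, a count that all 35 splits reach by construction in each, which says nothing about chance, and the highest other split called 1 gene in each. The 1648, 692 and 397 genes at an unadjusted p under 0.05 were reached by 4, 11 and 15 of 35 splits, with 3638, 4154 and 4683 in the highest other split. For SCCM against PGE2, 3 of 35 splits called at least the 1 gene of the labels. The split of SCCM replicates 1 and 4 and PGE2 replicates 1 and 2 from the rest, picked as the split with the most calls, called 2609 genes. This points to a structure of the samples that the treatments do not follow. At least as many gene lists as the labels gave (13, 10 and 4) were called by 12, 17 and 23 of 35 splits, with 19, 16 and 16 in the highest other split. The split with 19 moved only SCCM replicate 4 to the untreated side, so it keeps much of the treatment contrast.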
